A study of Mus musculus with 34 samples.

How the data were processed

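Multi-target chromatin integration labelling (mtChIL-seq) libraries from C2C12 cells were analysed. The labels describe 34 samples, of which 28 matched a column of the deposited table by name. The other 6 samples, all of a primary-antibody version of the method at 100 cells, were not analysed here, so the 4 comparisons planned with them were not made. Each library was assigned to a target (H3K4me3, CTCF, H3K27ac or Pol2S2P), a staining (dual, with both antibodies of a pair in the same cells, or single) and a number of cells (100, 1000 or 10000) from its title. The 28 libraries form 10 groups, of which the 8 dual groups hold 3 replicates each (24 libraries) and the 2 single groups hold 2 each (4 libraries). A further 4 columns of the table matched no sample and were not used. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

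The deposited values are raw counts per 1 kb bin of the mouse genome, made by the authors with no scaling. Per the submitters' processing notes, base calls were converted with bcl2fastq, reads were aligned with HISAT2 2.1.0 to GRCm38, and deepTools 3.3.1 was used. How duplicates, multiply mapped reads and antibody barcodes were treated is not given in the sources used here. The table holds 2728634 bins, of which 264542 were 0 in every column and 2631639 lie on the autosomes and X. Bins on the mitochondrial genome, Y and unplaced scaffolds were left out, as were 9 bins on chromosomes 2, 9 and 14 whose density was over 50 times the genome mean in every group. The remaining total per library ran from 719766 to 6653298 counts, which served as its library size. The reads carry no molecular identifiers in the sources used here, so intervals and floors cover counting error only.

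Genes were placed with a table of GRCm38.p6 coordinates for 21631 protein-coding genes on the autosomes and X. That table gives no strand and no sequence came with it, so the start of transcription was not known and no CTCF motif could be placed. Each gene was therefore represented by its marked end, the bins within 1 kb of whichever of its ends held more counts in libraries of a target outside the comparison. H3K27ac libraries chose the end for H3K4me3 and CTCF (19956 genes, with 1675 left out for a tie), and H3K4me3 libraries chose it for H3K27ac and Pol2S2P (19521 genes, with 2110 left out for a tie). Both choices took the same end in 77.7% of genes, and in 89.0% of the 9890 genes with at least 50 H3K4me3 counts. A marked end can be the downstream end of a gene. Of the marked ends, 16.8% and 18.1% by these choices shared bins with another gene. Gene interiors are the bins over 2 kb inside both ends of the 16449 genes of at least 5 kb. The comparisons planned at CTCF motifs were run on all 1 kb bins, with bins over 2 kb from every gene end called distal, and the planned share of counts at motifs became the share in the 1% of bins with the highest counts of each library. Both substitutions at motifs followed a rule written beforehand for a missing sequence, whereas the marked end was defined once the gene table had been seen to lack strand.

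Differences between groups were tested on the counts with edgeR 4.0.16 (quasi-likelihood test, filterByExpr, library sizes as above with no further scaling) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Only the libraries of the groups compared entered each fit. Counts scaled to a library of 1e6 (CPM) are means over replicates. Whether a difference between targets changed with the number of cells was tested as an interaction term. Shares of counts were compared by an exact two-sided permutation test stratified by the number of cells (400 permutations, smallest p 0.005). Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, in lists with at least 5 tested members, adjusted over lists within a comparison. The count adjusted over the list alone applies Benjamini-Hochberg adjustment to the members only. Tables were handled with the data.table package (1.17.8), numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

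The groups, tests, alternatives, 17 gene lists and the rule for named genes were set before the data were examined. The lists were myogenic regulators, contractile apparatus, matrix and cytoskeleton, housekeeping, ribosomal proteins, cell cycle, immediate early genes, Hox genes, other-lineage transcription factors, neuronal and glial markers, blood markers, liver markers, pluripotency, cohesin and CTCF, clustered protocadherins, replication-dependent histones, and olfactory and vomeronasal receptors. Named genes are the 5 with the largest fold change in each direction among those past the threshold, with no overlap of the groups, at least 20 counts in every library of the higher group and no shared bins, together with list members, and 3 bins per direction by the same rule. List members given as examples were picked after their values were seen, and some named genes are not reported here. Where every library of a group was at 0, a fold is a lower bound computed against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio is given as its 95% counting interval (exact binomial).

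Replicates were compared by a chi-square test over 10 kb windows. The statistic per degree of freedom was 1.10 to 1.90 in every pair of replicates, above the value for resampling of one library, so no library was counted as deposited more than once. The edgeR step was tested on simulated counts with 100 features changed at each fold size. Means were those of each feature pooled over both groups, and spreads were those fitted along the mean. All other features were unchanged, so the rates do not describe comparisons in which most features differ, such as H3K4me3 against CTCF. For marked ends of H3K4me3 against CTCF at 10000 cells (10356 features), 58% of 2-fold and 94% of 4-fold changes were recovered. For H3K27ac against Pol2S2P at 100 cells (1319 features) it was 36% and 85%, and for gene interiors at 1000 cells (12662 features) 74% and 98%. For CTCF bins between 10000 and 1000 cells (40168 features) it was 42% and 86%, and for Pol2S2P ends of dual against single staining (10417 features) 25% and 79%. False calls made up 2.56% to 7.14% of calls.

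Alternatives tried were TMM factors from 10 kb windows, DESeq2 1.42.0, no filter on low counts, keeping the 9 high bins, the replicate number as a block, ends within 2.5 kb, the whole gene in place of its interior, and each library left out in turn. After the data were seen, both gene ends together, distal bins only, and the share in the top 1% of bins after thinning every library to 719766 counts were added. DESeq2's size factors are medians over the features tested, so they centre those features on no difference.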

Results

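Chromatin integration labelling was used to map pairs of chromatin targets in the same small numbers of C2C12 cells, a mouse myoblast line that forms muscle fibres on differentiation. Antibodies on fixed cells carry a DNA probe that a transposase inserts into nearby DNA, and the flanking genome is copied into RNA and sequenced. H3K4me3, a histone mark of active gene starts, was stained together with CTCF, the zinc-finger protein that organises chromatin loops, in 1000 and 10000 cells. H3K27ac, a mark of active enhancers and gene starts, was stained together with Pol2S2P, RNA polymerase II phosphorylated on serine 2 of its tail during elongation, in 100 and 1000 cells. CTCF alone was stained in 10000 cells and Pol2S2P alone in 1000 cells. Each dual group holds 3 libraries (n = 3) and each single group 2 (n = 2). Counts on the autosomes and X ran from 719766 to 1317176 per library for H3K4me3 in 1000 cells and from 1417049 to 1973692 in 10000. CTCF libraries held 2074331 to 3262830 counts in 1000 cells, 4066700 to 5241420 in 10000, and 5159843 to 6653298 with single staining. H3K27ac libraries held 1158754 to 1302176 counts in 100 cells and 2906302 to 3139311 in 1000. For Pol2S2P the totals were 1255432 to 1580089 in 100 cells, 3159793 to 3645778 in 1000 and 2438251 to 3529256 with single staining.

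The 4 targets divided the genome differently. Marked gene ends (the bins within 1 kb of the gene end with more counts in libraries of another target) make up 2.12% of the bins by the choice of H3K27ac, and held 22.4% ± 0.592 (SD, n = 3) of H3K4me3 counts in 10000 cells and 7.24% ± 0.112 (SD, n = 3) of CTCF counts. Gene interiors, 35.7% of the bins, held 49.5% ± 0.282 (SD, n = 3) of Pol2S2P counts in 1000 cells, 44.7% ± 0.0542 (SD, n = 3) of H3K27ac counts in 1000 cells, and in 10000 cells 41.6% ± 0.0642 (SD, n = 3) of CTCF counts and 37.0% ± 0.14 (SD, n = 3) of H3K4me3 counts. Over both cell numbers H3K4me3 held 14.3 percentage points more of its counts at gene ends than CTCF (21.1% against 6.86%, exact stratified permutation p = 0.005, the smallest 400 permutations can give, higher in 6 of 6 same-numbered libraries). Pol2S2P held 4.66 points more of its counts in gene interiors than H3K27ac (49.3% against 44.7%, exact p = 0.005, 6 of 6). At ends chosen by H3K4me3, H3K27ac exceeded Pol2S2P by 0.223 points (5.01% against 4.79%, exact p = 0.01, 6 of 6). That last difference was 0.143 points with ends within 2.5 kb (exact p = 0.075) and -0.972 points when both gene ends were counted (exact p = 0.005). CTCF was less concentrated than H3K4me3, with 15.3% against 30.9% of counts in the 1% of bins with the highest counts (difference -15.6 points, exact p = 0.005, higher in 0 of 6). Depth was lower for H3K4me3, and a lower depth raises such a share. After thinning every library to 719766 counts, CTCF held 17.3% in 1000 and 18.1% in 10000 cells, and H3K4me3 30.1% and 33.2%. Taking same-numbered libraries as pairs gave p = 0.03125 by an exact sign-flip test, the smallest 6 pairs can give. This held for the H3K4me3, Pol2S2P and H3K27ac differences in main shares and for that in the top bins.

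**Figure D1:**
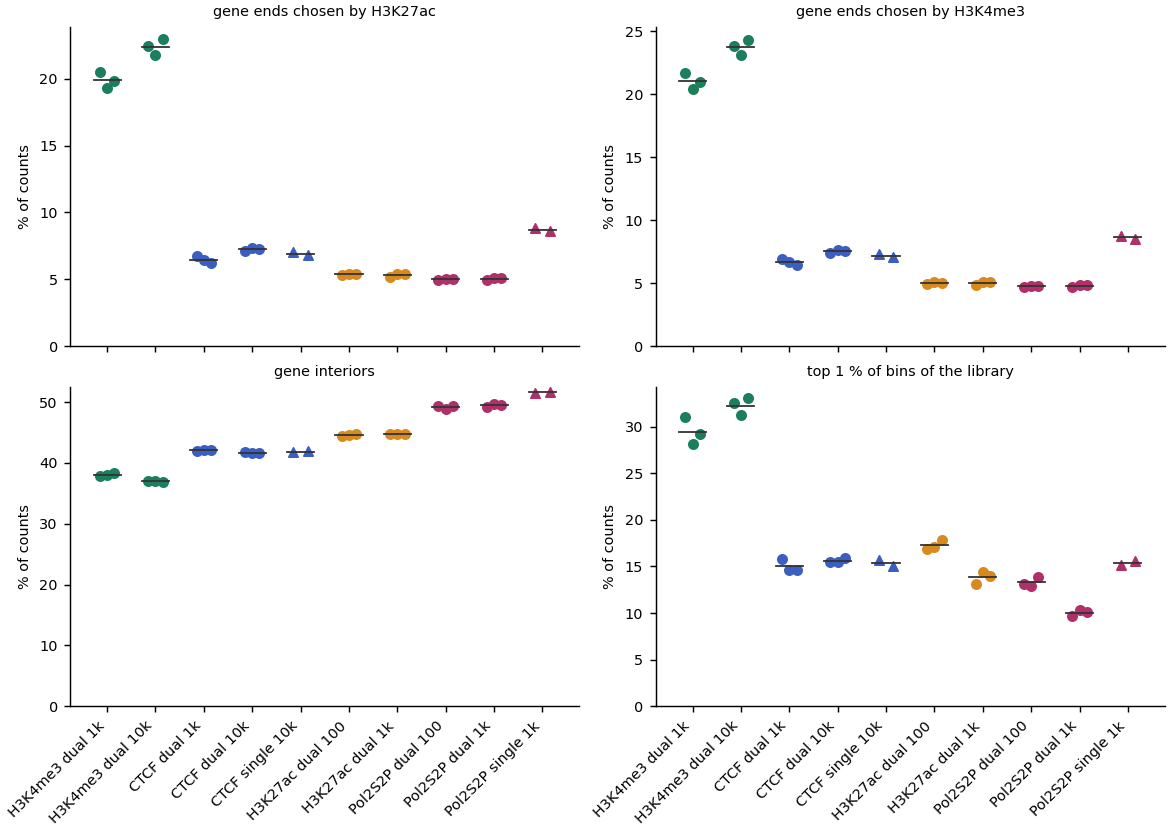
Percent of each library's counts at gene ends chosen by H3K27ac or by H3K4me3, in gene interiors, and in the 1% of bins with the highest counts; each point is a library (circles dual, triangles single staining) and each line a group mean. The 6 H3K4me3 libraries lie at or above 19.3% at gene ends chosen by H3K27ac, and the 2 libraries of Pol2S2P single staining average 8.63% at ends chosen by H3K4me3 against 4.81% with dual staining in 1000 cells.

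Gene groups separated along the same lines. At the marked ends of ribosomal protein genes H3K4me3 in 10000 cells stood at 42.0 times the genome mean per bin, at housekeeping genes at 35.3, at matrix and cytoskeleton genes such as collagens and fibronectin at 39.0, and at cell cycle genes at 35.9, against 11.6 over all genes. Olfactory and vomeronasal receptors, which are silent outside sensory neurons, stood at 0.346, transcription factors of other lineages at 1.39, liver markers at 0.801 and blood markers at 0.982. H3K27ac in 1000 cells was highest at matrix and cytoskeleton genes (11.6 times the genome mean) and immediate early genes (8.46), whereas Pol2S2P in 1000 cells was highest at ribosomal protein (9.29) and housekeeping genes (8.48). Neither exceeded 1.5 times the mean at markers of blood or liver. These are levels of the lists, with no test.

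**Figure D2:**
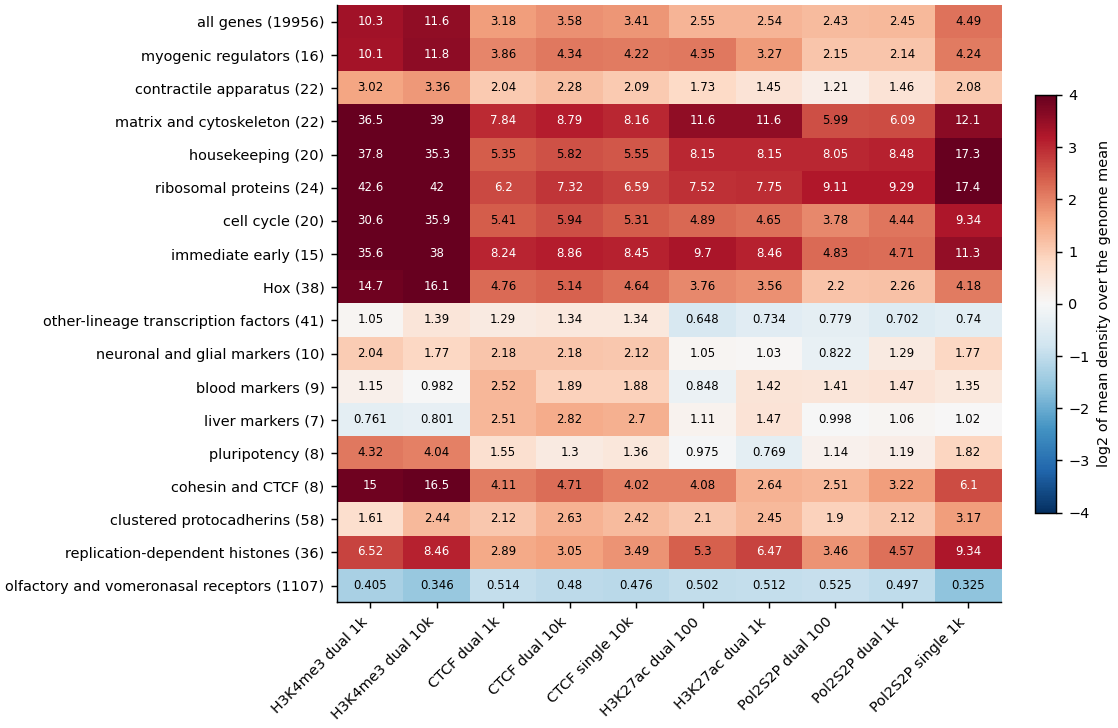
Mean density at the marked gene ends of each list, with the number of genes in parentheses for ends chosen by H3K27ac, relative to the genome mean per bin (printed values; colour on a log2 scale). Ribosomal protein genes reach 42.0 and olfactory and vomeronasal receptors 0.346 for H3K4me3 in 10000 cells.

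H3K4me3 was set against CTCF from the same staining, which asks how far the reads of each antibody were kept apart. In 10000 cells the largest H3K4me3 excess lay at Wdr82, a subunit of H3K4 methyltransferase complexes (chromosome 9, 106169571 to 106172570; log2 fold change 3.84 ± 0.22 SE; 37.3 ± 5.71 against 2.48 ± 0.545 CPM, SD, n = 3 each; adjusted p = 1.39e-28). Plk1, a mitotic kinase, followed at 3.82 ± 0.20, then Actg1, which encodes gamma-actin, at 3.64 ± 0.20, and Nol10 at 3.62 ± 0.22. CTCF exceeded H3K4me3 at Kctd16, an auxiliary subunit of GABA-B receptors (-3.41 ± 0.50), Shank2, a postsynaptic scaffold protein (-3.38 ± 0.49), and Pard6g, a cell polarity protein (-3.32 ± 0.43; chromosome 18, 80117676 to 80120675). Psg16 and Xdh, also among the 5 largest in this direction, had 2 and 3 H3K4me3 counts in all, for ratios of H3K4me3 to CTCF between 0.00658 and 0.204 and between 0.0192 and 0.286. The liver gene Apob lay at -3.01 ± 0.40 and Gad1, which makes GABA in neurons, at -2.33 ± 0.45.

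Most members of several lists were higher in H3K4me3, as were 8500 of all 10356 marked ends. All 24 tested ribosomal protein genes were higher (Rpl8 3.37 ± 0.17, Rps9 3.28 ± 0.18), as were 19 of 19 cell cycle genes (Ccnb1 3.18 ± 0.22, Mki67 2.97 ± 0.21), 19 of 20 housekeeping genes (Gapdh 2.82 ± 0.18), 18 of 20 matrix and cytoskeleton genes (Col3a1 2.80 ± 0.16, Fn1 2.78 ± 0.16, Vim 2.59 ± 0.12) and 6 of 6 genes of cohesin and CTCF (median 1.84, but -0.04 by DESeq2 with 1 called). Of the others, 13 of 15 immediate early genes were higher and 1 lower, and of 19 Hox genes 13 were higher (Hoxa11 2.89 ± 0.16) and 4 lower (Hoxd11 -2.18 ± 0.47). Among 30 histone genes 24 were higher and 1 lower (median 1.32), whereas DESeq2 gave 2 higher and 9 lower (median -0.57). Of 8 myogenic regulators 6 were higher, among them Myf5 (2.59 ± 0.17), a transcription factor that acts early in muscle formation, and 2 were lower, Myod1 (-2.39 ± 0.36) and Megf10. Contractile genes were mixed, with 5 of 8 higher and 2 lower (median 1.29, but -0.60 by DESeq2 with 0 higher and 3 lower, and -0.06 with both gene ends); the lower ones were the troponins Tnnt3 (-1.95 ± 0.41) and Tnni1 (-1.73 ± 0.34). Clustered protocadherins (60 members) and olfactory or vomeronasal receptors (1470 members) each had 7 of 10 tested lower and 1 higher. An end with few H3K4me3 counts passed the filter on low counts only through CTCF, which favours lower calls. Neither these counts nor camera therefore describe the whole lists, and the same limit applies to other lists with few members tested. The small sets of other-lineage transcription factors and neuronal and glial markers each had 1 of 3 higher and 2 lower, blood markers had 1 lower of 1, liver markers 1 lower of 2, and pluripotency 1 higher of 1. Adjusted over the list alone, the count differed only for histones, with 23 higher. Camera placed ribosomal (adjusted p = 1.36e-05), housekeeping and cell cycle (both 0.000275) and matrix genes (0.00126) above the other genes, and protocadherins and olfactory receptors (both 3.04e-05), contractile genes (0.0226) and histones (0.0227) below them. None of these held with an estimated correlation (adjusted p = 0.0548, 0.188, 0.0655, 0.122, 0.0812, 0.0548, 0.125 and 0.188 in that order).

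By edgeR 9307 of 10356 marked ends differed, 8500 higher in H3K4me3 and 807 lower, with a median log2 fold change of 1.89. Part of this split follows the scaling. TMM gave a median of 2.21, and DESeq2, which centres the ends tested on no difference, called 5427, of which 46.7% were higher in H3K4me3 against 91.3% by edgeR.

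In 1000 cells 7577 of 8357 marked ends differed, 7177 higher and 400 lower (median 2.11, or 2.22 by TMM). Actg1 (4.40 ± 0.31), Nop58, a component of ribosomal RNA modification complexes (4.06 ± 0.22), Rabggtb, which prenylates Rab proteins (4.01 ± 0.22), and Lpar6 (3.99 ± 0.24) led the rise. Klhdc9 was lower by the widest margin among genes with more than 3 H3K4me3 counts (-3.40 ± 0.42). Cxcl3, Colgalt2, Klk14 and Tafa2 held 2 or 3 H3K4me3 counts, with ratios to CTCF of at most 0.212, 0.253, 0.248 and 0.27 at the upper end of their intervals. Myf5 (2.74 ± 0.27) was again higher, and Myod1 lower, with 2 H3K4me3 against 69 CTCF counts (ratio between 0.00935 and 0.295). All 24 ribosomal protein genes, all 19 housekeeping genes, 18 of 19 cell cycle genes and 18 of 20 matrix genes were higher, in the same numbers adjusted over the list alone; their camera calls did not hold with an estimated correlation (adjusted p = 0.516 for the first pair and 0.638 for the second). DESeq2 called 3009 ends, of which 41.7% were higher in H3K4me3 against 94.7% by edgeR.

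The calls at both cell numbers overlapped. Of 8351 marked ends tested at both, 7132 were higher in H3K4me3 at each, where independent lists would share 6442, and 350 were lower at each, where independent lists would share 20.1. Fold changes had the same sign in 97.9% of ends and correlated across genes at r = 0.936, although genes are not independent replicates. The test of the difference between cell numbers called 0 of 9950 ends by edgeR, with 688 at an unadjusted p under 0.05; no other tool was run for it.

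CTCF binding was set against H3K4me3 over all 1 kb bins, in place of CTCF motifs. Bins with CTCF counts and none of H3K4me3 in any library of 10000 cells were led by 3 intervals outside protein-coding genes. The first (chromosome 3, 101812586 to 101813585) had 8.90 ± 1.73 CPM of CTCF (SD, n = 3) and was at least 14.1-fold higher, taking the floor of 3 counts over the group. The others lay on chromosome 7 (143463416 to 143464415, at least 10.6-fold) and chromosome 3 (92510626 to 92511625, at least 10.5-fold). The bins with the largest H3K4me3 excess lay in Togaram1 (chromosome 12, 64966736 to 64967735, -4.63 ± 0.32), BC005537 (-4.43 ± 0.28) and Pgam1, a glycolytic enzyme gene (-4.40 ± 0.28). Of 44023 bins tested in 10000 cells, 12942 were higher in CTCF and 23741 lower. The higher count moved together with the number of bins tested, at 7431, 7451 and 7325 without CTCF replicates 1, 2 and 3 (32495, 32455 and 32312 tested) and 19487, 18819 and 19570 without H3K4me3 replicates 1, 2 and 3 (71734, 71058 and 71583 tested). Away from gene ends the balance turned: among 22264 distal bins, 11203 were higher in CTCF and 5565 lower. The median over all bins was -1.03 (-1.35 by TMM), and DESeq2 called 30195 bins, of which 58.4% were higher in CTCF against 35.3% by edgeR.

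In 1000 cells the leading CTCF bin lay in Ptprr, a tyrosine phosphatase gene (chromosome 10, 116207531 to 116208530; 12.8 ± 6.05 CPM, SD, n = 3, against 0; at least 12.3-fold). Intergenic bins on chromosome 2 (93474621 to 93475620) and chromosome 1 (179859271 to 179860270) followed at no less than 10.9-fold and 9.70-fold. Bins in Wdr43 (-5.67 ± 0.46), Ppp1r15b (-5.23 ± 0.38) and Dr1 (-5.13 ± 0.39) held the largest H3K4me3 excess. Of 16589 bins, 3228 were higher in CTCF and 11928 lower, and of 5559 distal bins 2724 were higher and 2024 lower. The median was -2.27 (-2.38 by TMM), and DESeq2 called 6313 bins, of which 78.5% were higher in CTCF against 21.3% by edgeR. Leaving out H3K4me3 replicate 1 gave 23562 calls and leaving out replicate 3 gave 22932, against 15156. Those higher in CTCF were 7963, 7271 and 7471 without H3K4me3 replicates 1, 2 and 3 and 1932, 1961 and 2074 without CTCF replicates 1, 2 and 3. Of 16481 bins tested at both cell numbers, 3046 were higher in CTCF at each (637 for independent lists) and 11753 lower (8727), with the same sign in 97.8% and r = 0.955 across bins.

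**Figure D3:**
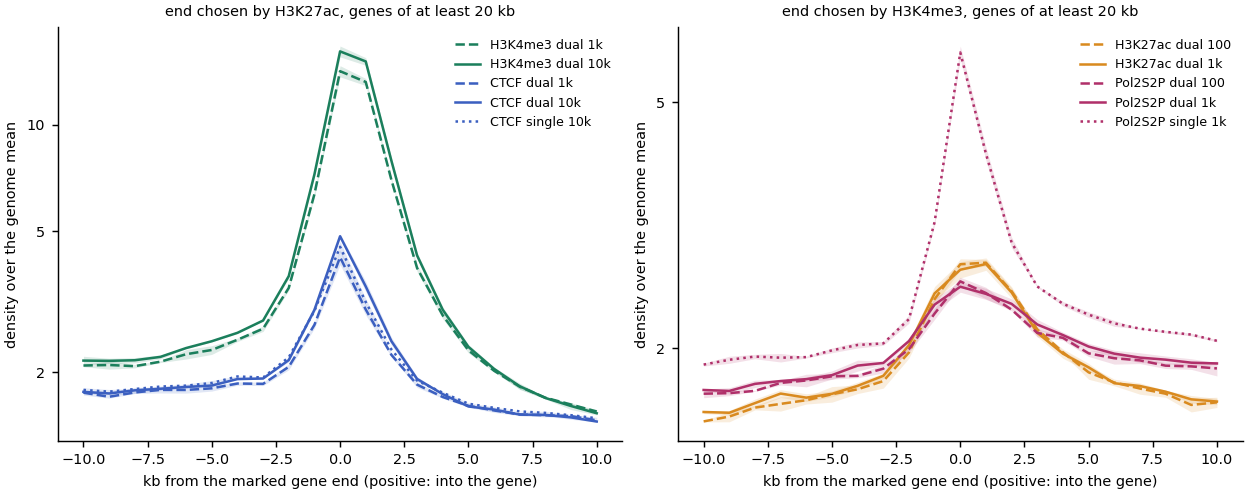
Mean density around the marked end of genes of at least 20 kb, per 1 kb bin from 10 kb outside to 10 kb inside the gene, relative to the genome mean (log axis; lines are group means, bands 1 SD over 2 or 3 libraries). At the end bin H3K4me3 in 10000 cells stood at 16.1, CTCF at 4.84, Pol2S2P with single staining at 6.02 and Pol2S2P with dual staining in 1000 cells at 2.51.

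H3K27ac was set against Pol2S2P from the same staining at marked ends chosen by H3K4me3. In 1000 cells H3K27ac was highest relative to Pol2S2P at Prss56, a serine protease gene (chromosome 1, 87181646 to 87184645; log2 fold change 2.58 ± 0.36 SE; 10.8 ± 3.54 against 1.76 ± 0.793 CPM, SD, n = 3 each; adjusted p = 4.96e-10). Aqp5, a water channel (2.25 ± 0.27), Arl4c, a small GTPase (2.24 ± 0.36), and Epha2, an ephrin receptor (2.17 ± 0.33), followed. Pol2S2P was highest relative to H3K27ac at Naprt, an enzyme of NAD synthesis (-2.86 ± 0.38), Nfe2l3, a transcription factor of the NRF family (-2.66 ± 0.21; chromosome 6, 51456791 to 51459790), Nanos1 (-2.62 ± 0.39), Msh4, a meiotic recombination gene (-2.37 ± 0.25), and Srrm2, a splicing factor (-2.37 ± 0.35). Among extracellular matrix genes Col3a1 (2.05 ± 0.25), Col1a2 (1.62 ± 0.29) and Fn1 (1.59 ± 0.29) were higher in H3K27ac, and Ccnd1, which encodes cyclin D1, lay at 2.02 ± 0.29.

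Matrix and cytoskeleton genes rose in H3K27ac, with 15 of 20 higher and 0 lower (17 adjusted over the list alone). Hox genes had 8 of 12 higher (10 adjusted over the list alone; Hoxa11 1.44 ± 0.34, Hoxc11 1.13 ± 0.25), immediate early genes 5 of 11 (6 higher and 1 lower adjusted over the list alone; Fosl2 1.59 ± 0.29, Klf6 1.51 ± 0.23, Myc 1.25 ± 0.18), histones 9 of 30 (12 adjusted over the list alone), and myogenic regulators 3 of 6 (4 adjusted over the list alone; Myf5 1.11 ± 0.30). Ribosomal protein genes had 4 of 25 lower and 0 higher (Rpl13 -1.13 ± 0.24, Rpl19 -0.96 ± 0.24). Housekeeping genes had 1 of 20 higher and 2 lower (median 0.19, but -0.66 with both gene ends, where 13 were lower), namely Actb, which encodes beta-actin (-2.21 ± 0.21), and Ywhaz (-1.16 ± 0.24). No protocadherin of 23 and no contractile gene of 3 was called, 1 of 15 cell cycle genes was higher, and 2 of 6 olfactory receptors were higher (5 adjusted over the list alone). Camera set matrix (adjusted p = 7.22e-10), immediate early and Hox genes (both 0.00039), histones (0.00202), olfactory receptors (0.0159) and myogenic regulators (0.0374) above the rest and ribosomal protein genes (0.0148) below. None held with an estimated correlation (adjusted p = 0.101, 0.125, 0.125, 0.332, 0.125, 0.141 and 0.125 in that order).

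Of 7107 marked ends 1369 differed by edgeR, 866 higher in H3K27ac and 503 lower (median 0.09), and DESeq2 called 549. The choice of gene end changed the direction: with both ends of each gene 2479 were called, of which 27.7% were higher in H3K27ac against 63.3% with the marked end, and Col1a2 and Fosl2 turned to -0.12 and -0.13. Ends widened to 2.5 kb gave 2364 calls, 1209 of them higher.

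In 100 cells 322 of 1319 marked ends were higher in H3K27ac and 109 lower. Tnni3k, a kinase that binds cardiac troponin I (3.23 ± 0.44), Wfdc1 (2.94 ± 0.42), Col3a1 (2.44 ± 0.41), Krt80, a keratin (2.30 ± 0.32), and Hspb7, a small heat shock protein of muscle (2.29 ± 0.39), led the higher ends. Klb, a co-receptor for fibroblast growth factors (-3.27 ± 0.50), Nfe2l3 (-2.90 ± 0.35), Ccnb1ip1 (-2.86 ± 0.51), Fam161a (-2.71 ± 0.46) and Cd68 (-2.56 ± 0.36) led the lower ones. Matrix genes had 6 of 13 higher (7 adjusted over the list alone), immediate early genes 5 of 7 (Fosl2 2.64 ± 0.49), Hox genes 4 of 5 and ribosomal protein genes 3 of 16 lower; Myf5 lay at 2.15 ± 0.45 and Ccnd1 at 2.20 ± 0.47. No camera call held with an estimated correlation (adjusted p = 0.234 for matrix and ribosomal genes, 0.296 for immediate early genes). The median of all ends was 0.41, DESeq2 called 205 with 35.1% higher in H3K27ac against 74.7% by edgeR, and with both gene ends 666 were called, 36.8% of them higher. Without H3K27ac replicate 2 the count was 262 against 431.

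Of 1318 ends tested at both cell numbers, 257 were higher in H3K27ac at each (107 for independent lists, Fisher's exact p = 9.9e-91) and 88 lower (11.6, Fisher's exact p = 5.6e-79). The same sign was seen in 83.8% and r was 0.843 across genes. Gene ends are not independent replicates, so the Fisher p-values overstate the evidence from these libraries. The test of the difference between cell numbers called 0 of 6458 ends by edgeR, with 303 at an unadjusted p under 0.05, and 1 without H3K27ac replicate 2 or replicate 3 of 100 cells.

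Gene interiors, where elongating polymerase travels, were compared in the opposite direction. In 1000 cells Pol2S2P exceeded H3K27ac at Tbr1, a transcription factor of cortical neurons (chromosome 2, 61805751 to 61811750; 2.65 ± 0.45; 7.19 ± 1.86 against 1.10 ± 0.386 CPM, SD, n = 3 each; adjusted p = 8.48e-08), Cryba1, a lens crystallin (2.64 ± 0.43), Fam8a1 (2.43 ± 0.39), Noc2l, a ribosome biogenesis factor (2.27 ± 0.33), and its neighbour Samd11 (2.19 ± 0.36). H3K27ac exceeded Pol2S2P within Serpinb1b (-1.92 ± 0.18), Tmem182, a membrane protein of muscle (-1.90 ± 0.08; chromosome 1, 40807836 to 40854835), Serpinb1c (-1.64 ± 0.09), Foxn1, a regulator of thymic epithelium (-1.64 ± 0.10), and Vamp5, a muscle SNARE protein (-1.62 ± 0.20). All 8 genes of cohesin and CTCF rose in Pol2S2P (Smc1a 1.13 ± 0.17, Stag2 1.02 ± 0.11), and so did 10 of 14 cell cycle genes (11 adjusted over the list alone; Cdk1 1.34 ± 0.17, Top2a 1.09 ± 0.12, Mki67 1.04 ± 0.18) and 5 of 7 housekeeping genes (the glycolytic Pgk1 1.53 ± 0.21 and Pkm 1.51 ± 0.12). Matrix genes were mixed, 6 of 15 higher and 1 lower, Col1a1 (-0.95 ± 0.24), or 2 lower adjusted over the list alone (median 0.18, but -0.13 by DESeq2 with 5 higher and 5 lower). Hox genes had 3 of 8 lower (Hoxc6 -1.28 ± 0.17; median 0.09, -0.21 by DESeq2) and neuronal and glial markers 2 of 9 (Mbp -1.16 ± 0.09). Other-lineage transcription factors had 3 of 14 higher and 2 lower (median 0.14, but -0.16 by DESeq2 with 1 higher and 3 lower), and olfactory receptors 2 of 52 higher and 2 lower (median 0.05, -0.25 by DESeq2). Camera set cohesin and CTCF genes above the rest (adjusted p = 8.49e-06), and neuronal markers (0.0301), protocadherins and olfactory receptors (both 0.0384) below. None held with an estimated correlation (adjusted p = 0.229, 0.229, 0.684 and 0.229).

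Of 12662 interiors 4825 were higher in Pol2S2P and 1256 lower in 1000 cells (median 0.31, 0.23 by TMM), and DESeq2 called 3752, of which 44.4% were higher against 79.3% by edgeR. In 100 cells 2784 of 9764 were higher and 883 lower, led by Nfe2l3 (2.72 ± 0.34), Dgat1, an enzyme of triglyceride synthesis (2.47 ± 0.44), the mitochondrial protease Lonp1 (2.44 ± 0.42), the exosome nuclease Dis3 (2.34 ± 0.33) and the splicing factor Sfpq (2.18 ± 0.20). Tmem182 (-2.06 ± 0.13), Foxn1 (-1.84 ± 0.16), Pde6h (-1.82 ± 0.39), Ankrd66 (-1.72 ± 0.40) and Ccdc172 (-1.70 ± 0.20) led the lower ones. Again all 8 cohesin and CTCF genes were higher (camera adjusted p = 0.000104, and 0.0945 with an estimated correlation), with 5 of 8 cell cycle genes (6 adjusted over the list alone). DESeq2 called 2075, of which 38.1% were higher against 75.9% by edgeR (median 0.31). Among 9764 interiors tested at both cell numbers 2538 were higher at each (1220 for independent lists) and 780 lower (108), with the same sign in 85.6% and r = 0.834 across genes.

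The effect of the number of cells was tested within each target. H3K4me3 at marked ends was higher in 10000 than in 1000 cells at 357 of 8502 ends and lower at 6 (median 0.20, 0.36 by TMM). Ccl7, a chemokine (chromosome 11, 82045671 to 82048670; 1.80 ± 0.29; 29.2 ± 4.43 against 8.43 ± 2.37 CPM, SD, n = 3 each; adjusted p = 3.43e-06), Sec16b (1.74 ± 0.38), the integrin Itgb8 (1.61 ± 0.35), Tmem120b (1.52 ± 0.38) and the mitophagy receptor Bnip3 (1.44 ± 0.41) led. The lower ends included Tmem95 (-0.92 ± 0.21), Coq10b and Dynap (both -0.74, SE 0.22 and 0.17) and the ribosomal protein gene Rpl13 (-0.72 ± 0.21), the 1 of 24 ribosomal protein genes called. Matrix genes had 2 of 19 higher, among them Col3a1 (0.58 ± 0.17), histones 2 of 21 (4 adjusted over the list alone), cell cycle genes 1 of 19 (Mcm6 0.82 ± 0.22; 3 adjusted over the list alone), and immediate early genes 1 of 14 (Klf4 0.68 ± 0.20; 2 adjusted over the list alone); DESeq2 called none of these and gave medians of -0.05 for matrix, -0.02 for cell cycle and -0.05 for immediate early genes. No housekeeping gene of 19 was called. Camera set housekeeping (adjusted p = 8.07e-05) and ribosomal protein genes (0.000693) below the rest, which did not hold with an estimated correlation (adjusted p = 0.304 for both). DESeq2 called 3 ends, 0.0% of them higher against 98.3% by edgeR, and TMM called 1732. Without any 1 of 5 libraries the count of 363 fell to 135 and 102 (1000 cells, replicates 2 and 3) or to 102, 181 and 68 (10000 cells, replicates 1, 2 and 3).

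CTCF was tested between cell numbers over single bins and not at marked ends, so its calls cannot be set against those of H3K4me3. The share of counts at marked ends rose in both, from 6.47% to 7.24% for CTCF and from 19.9% to 22.4% for H3K4me3. Of 40168 CTCF bins 73 were higher in 10000 cells and 20 lower (median 0.12), 44 and 20 of them distal. Bins in Smyd3 (2.00 ± 0.41), in Mrc2 (1.94 ± 0.41) and in an interval of chromosome 2 (144212416 to 144213415, 1.68 ± 0.41) were highest. The lower ones led with intervals near the annotated start of chromosomes 9 (3017991 to 3018990, -1.37 ± 0.25, and 3026991 to 3027990, -1.05 ± 0.23) and 12 (3108991 to 3109990, -0.98 ± 0.12). DESeq2 called 13, 0.0% of them higher against 78.5% by edgeR, and 4645 passed an unadjusted p of 0.05. Without replicate 3 of 1000 cells 54 bins were called, and without replicates 1, 2 and 3 of 10000 cells 42, 31 and 36. For H3K27ac between 1000 and 100 cells edgeR called 0 of 3891 marked ends, with 220 at an unadjusted p under 0.05 and 0 by DESeq2; without replicate 2 of 100 cells 3 were called, and without replicate 2 of 1000 cells 1. No list gave a call there, and camera's calls for protocadherins and histones (adjusted p = 0.000103 for both) did not hold with an estimated correlation (adjusted p = 0.777). For Pol2S2P in gene interiors 2 of 12075 differed, Iqank1 (0.96 ± 0.19 higher in 1000 cells) and Myo3a, an unconventional myosin (-0.67 ± 0.12), with 790 at an unadjusted p under 0.05 and 1 by DESeq2. Without replicate 1 of 100 cells 5 were called, and without replicates 1 and 3 of 1000 cells 1 and 0.

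CTCF with dual staining was set against CTCF alone in 10000 cells, which asks what a second antibody does to the first. At 12512 marked ends edgeR called 0, with 1277 at an unadjusted p under 0.05 and 0 by DESeq2 (median 0.07). The 17 lists likewise gave 0 calls; adjusted over the list alone 1 housekeeping, 1 ribosomal protein and 1 olfactory receptor gene were higher and 1 blood marker lower. Camera set histones below the rest (adjusted p = 0.00337), which did not hold with an estimated correlation (adjusted p = 0.331). Over all bins 79 of 82620 differed, 35 higher and 44 lower, with 13 and 43 among distal bins. The highest were an interval of chromosome 8 (85036656 to 85037655, 1.47 ± 0.32), a bin in Wls (1.44 ± 0.31) and a bin in Atad2 (1.39 ± 0.26); the lowest lay in Osbpl3 (-1.94 ± 0.42) and in intervals of chromosomes 5 (144370416 to 144371415, -1.89 ± 0.37) and 4 (3415991 to 3416990, -1.81 ± 0.36). DESeq2 called 0 bins, and leaving out any 1 of the 5 libraries left 0 to 4. Ends within 2.5 kb gave 48 calls, 40 higher, and without the first single library, which leaves 1 library in that group, 2 ends were called. Profiles of both stainings correlated at r = 0.938 on average over 6 pairs of libraries, beside 0.936 among dual replicates.

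Pol2S2P with dual staining differed from Pol2S2P alone in 1000 cells. Marked ends held 4.81% ± 0.0872 (SD, n = 3) of counts with dual and 8.63% ± 0.179 (SD, n = 2) with single staining, and gene interiors 49.5% ± 0.282 and 51.6% ± 0.0874. The largest falls in dual staining lay at Fam20c, a kinase of secreted proteins (chromosome 5, 138753436 to 138756435; -2.88 ± 0.46; 1.22 ± 0.826 against 8.98 ± 0.522 CPM, SD, n = 3 and n = 2; adjusted p = 1.43e-06), Atp2b1, a calcium pump (-2.76 ± 0.40), Tsc22d1 (-2.76 ± 0.44), Dipk2a (-2.56 ± 0.43) and Prmt3, an arginine methyltransferase (-2.45 ± 0.40). Serpind1, a thrombin inhibitor gene, rose (0.93 ± 0.41). The fall took in 22 of 25 ribosomal protein genes, 28 of 32 histones (30 adjusted over the list alone), 19 of 21 housekeeping genes (Actg1 -1.47 ± 0.26), 18 of 20 cell cycle genes (Ccne1 -2.02 ± 0.54), 13 of 14 immediate early genes (Klf4 -2.01 ± 0.45), 7 of 8 myogenic regulators, 12 of 20 matrix genes (Fn1 -1.55 ± 0.32), 12 of 20 Hox genes, 3 of 6 contractile genes and 4 of 8 cohesin and CTCF genes (3 adjusted over the list alone), but DESeq2 called 0 in every one of these lists and gave medians of 0.02 for ribosomal protein, 0.08 for histone, 0.11 for matrix, 0.17 for contractile and 0.21 for cohesin and CTCF genes. Protocadherins had 2 of 24 lower (1 adjusted over the list alone; median -0.58, 0.40 by DESeq2), and olfactory receptors 2 of 10 higher and 2 lower (2 and 1 adjusted over the list alone). Relative to the other genes camera set olfactory receptors (adjusted p = 1.05e-06) and protocadherins (0.0326) higher, and immediate early and housekeeping (both 0.00268), ribosomal protein (0.00814) and histone genes (0.0287) lower. None held with an estimated correlation (adjusted p = 0.218, 0.705, 0.218, 0.519, 0.519 and 0.58 in that order).

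Of 10417 marked ends 6594 were lower with dual staining and 40 higher by edgeR (median -0.99, -1.16 by TMM). DESeq2, which removes that median, called 0, with 7121 ends at an unadjusted p under 0.05 by edgeR. Without the first single library, which leaves a group of 1 with no spread of its own, 3776 ends were called in place of 6634.

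Within genes the median was near 0 (-0.07, -0.24 by TMM), with 1455 of 13314 interiors higher with dual staining and 2020 lower. Chrna7, a nicotinic receptor subunit (2.36 ± 0.41; 10.5 ± 1.49 against 2.08 ± 0.538 CPM, SD, n = 3 and n = 2; adjusted p = 1.22e-06), Rassf9 (2.17 ± 0.45), Adgre1, a macrophage receptor (1.93 ± 0.30), Csta2 (1.86 ± 0.46) and Hcrtr2, an orexin receptor (1.80 ± 0.37), rose. Cdkn1a, the cell cycle inhibitor p21 (-2.04 ± 0.26), Nudc (-1.66 ± 0.35), Zfp61 (-1.64 ± 0.42), Ndufa4l2 (-1.62 ± 0.26) and the polymerase subunit Polr2c (-1.60 ± 0.45) fell. Olfactory and vomeronasal receptors had 19 of 58 higher and 0 lower (22 adjusted over the list alone; camera adjusted p = 1.57e-07). Matrix genes had 9 of 15 lower (10 adjusted over the list alone; Vim -0.99 ± 0.13; camera 4.54e-07), housekeeping genes 6 of 9 (7 adjusted over the list alone; Eno1 -1.01 ± 0.17, Eef2 -1.26 ± 0.41) and cell cycle genes 9 of 17 (10 adjusted over the list alone; Mcm3 -0.85 ± 0.26). Olfactory and matrix genes did not hold with an estimated correlation (adjusted p = 0.0676 for both). Of 38 protocadherins, whose interiors share bins, 13 were higher and 20 lower. DESeq2 called 1474 interiors, of which 61.4% were higher against 41.9% by edgeR, and TMM 4769, of which 18.3% were higher. With 1 single library left, 2051 were called in place of 3475 when the first was left out.

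Muscle regulators were measured over the whole gene with 1 kb on either side, since the marked end of Myod1 lay at the high-coordinate end of the gene. Myf5 stood at 32.1 ± 1.97 times the genome mean in H3K4me3 in 10000 cells (SD, n = 3) and Six4 at 17.5 ± 1.76. Myod1, a master regulator of muscle fate (chromosome 7, 46376474 to 46379092), stood at 1.13 ± 0.474 on 13 counts, and Myog, which drives differentiation, at 1.04 ± 0.455 on 11. H3K27ac in 1000 cells gave 6.84 ± 0.211 at Myf5 and 0.192 ± 0.0759 at Myod1 on 4 counts. CTCF reads were plentiful at Myod1, with 5.27 ± 0.108 times the mean in 10000 cells on 171 counts. Myh3, an embryonic myosin gene, likewise had more CTCF (5.89 ± 0.43) than H3K4me3 (2.64 ± 0.379). Pax7, a factor of muscle stem cells, stood at 0.323 ± 0.0554 in H3K4me3 and Ckm, muscle creatine kinase, at 0.652 ± 0.403. These values are averages over whole genes, so signal confined to a gene end gives a lower value in a longer gene. Genes of different length therefore cannot be compared directly, and a low value does not exclude signal at the gene start.

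**Figure D4:**
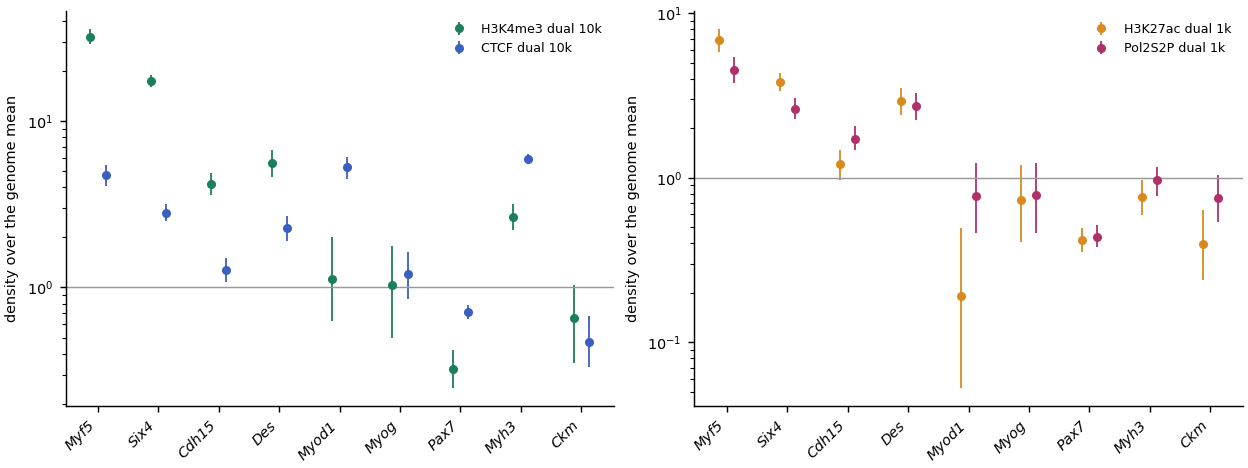
Density over 9 muscle genes with 1 kb on either side, relative to the genome mean per bin (log axis, grey line at 1), for H3K4me3 and CTCF in 10000 cells and for H3K27ac and Pol2S2P in 1000 cells; points are group means over 3 libraries and bars 95% intervals of the summed count. Myf5 and Six4 reach 32.1 and 17.5 in H3K4me3, and Myod1 1.13. Values are averages over whole genes, so genes of different length cannot be compared directly.

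Correlations over both ends of each gene summed up the libraries. Within a group the mean r between replicates ran from 0.689 for H3K27ac in 100 cells to 0.952 for H3K4me3 in 10000 cells. H3K4me3 in 10000 cells correlated at 0.865 with Pol2S2P alone and at 0.798 with Pol2S2P of the dual staining in 1000 cells. These values are across genome features in pairs of libraries, which are not independent replicates.

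**Figure D5:**
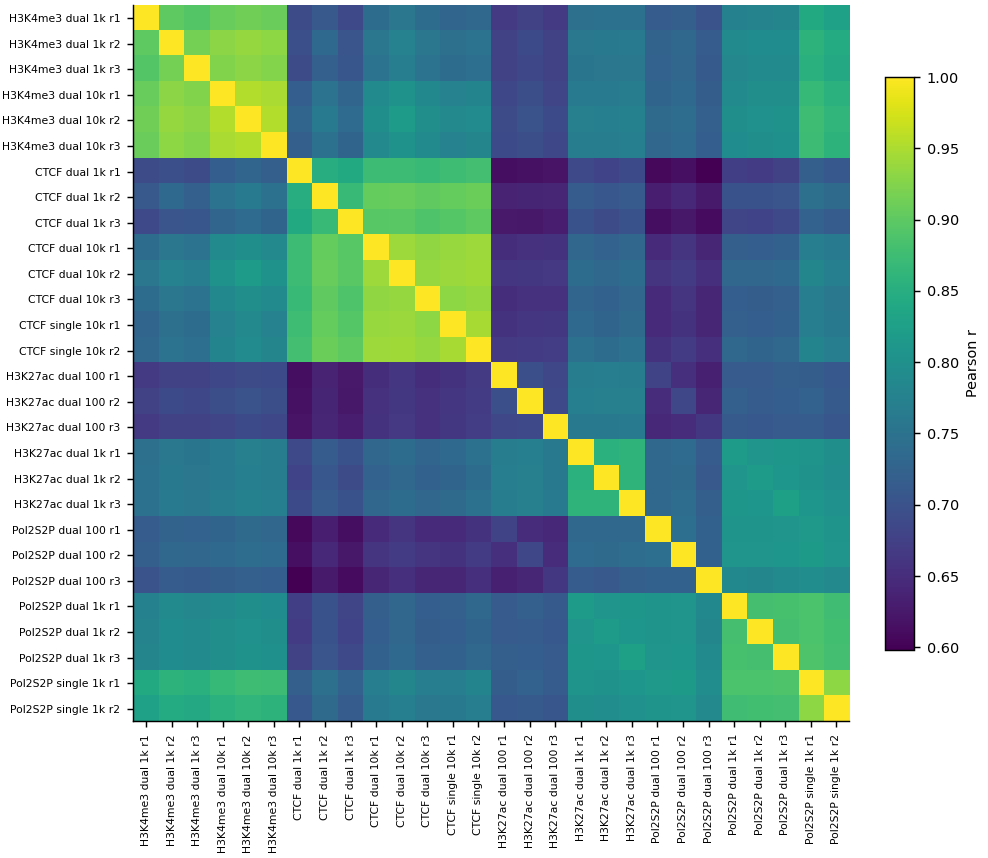
Pearson correlation of log2 CPM at both gene ends between all 28 libraries, ordered by target and group. Replicates of H3K4me3 in 10000 cells average 0.952 and those of H3K27ac in 100 cells 0.689.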

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

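Reads on the mitochondrial genome were left out of every test. They made up 0.457% of all counts for H3K27ac and 0.331% for Pol2S2P in 100 cells, and 0.237% and 0.184% in 1000 cells with dual staining. With Pol2S2P alone the mean was 0.101%. For H3K4me3 the mean was 0.138% in 1000 cells and 0.0647% in 10000, and for CTCF 0.0733% and 0.0416%, with 0.0471% for CTCF alone. The share was thus lower in the larger number of cells for all 4 targets, and no test was made of it. Whether it reflects the ratio of transposase to DNA was not tested.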

How the results depend on the processing

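Both gene ends, distal bins only and the share in the top 1% of bins after thinning were added after the data were seen, and the other alternatives were planned. CTCF motifs were not placed for want of sequence, so the planned relaxed motif threshold was not run, and no DESeq2 fit was planned for the interactions.

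DESeq2 changes both the scaling and the test, and which of them lowered its counts was not tested. It called 5427 marked ends of H3K4me3 against CTCF in 10000 cells and 3009 in 1000 cells, 6313 bins in 1000 cells, and 549 and 205 ends of H3K27ac against Pol2S2P in 1000 and 100 cells. In gene interiors of Pol2S2P against H3K27ac it called 3752 and 2075. Between cell numbers it called 3 H3K4me3 ends, 13 CTCF bins and 1 Pol2S2P interior. For dual against single staining it called 0 CTCF bins, 0 Pol2S2P ends and 1474 Pol2S2P interiors. TMM raised the H3K4me3 ends that differed between cell numbers from 363 to 1732, nearly all upward (1727), as its median moved up.

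With no filter on low counts 22822 CTCF and H3K4me3 bins differed in 1000 cells, 162 H3K4me3 ends and 14 CTCF bins between cell numbers, 1 H3K27ac end between cell numbers, and 0 CTCF bins between stainings. Ends within 2.5 kb gave 2364 and 922 calls for H3K27ac against Pol2S2P in 1000 and 100 cells and 48 for CTCF dual against single. The share of H3K27ac over Pol2S2P at those wider ends was 0.143 points (exact p = 0.075). With both gene ends 2479 and 666 ends were called for that pair and 3 for CTCF dual against single. There the difference in shares was -0.972 points (exact p = 0.005), and Col1a2 and Fosl2 turned to -0.12 and -0.13 in 1000 cells (adjusted p = 0.658 and 0.665). Both ends bring in the end with fewer H3K4me3 counts, where Pol2S2P held more than H3K27ac; any further cause was not tested. Among distal bins only, 16626 differed between CTCF and H3K4me3 in 10000 cells (11124 higher in CTCF), 4742 in 1000 cells (2720 higher) and 48 between CTCF stainings (10 higher).

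The replicate number was entered as a block, although the titles, which give both targets of a dual staining the same numbers, do not state that a number marks the same cells. The check of pairing gave correlations of deviations of 0.0623 to 0.0813 and 0.0491 to 0.0579 for same-numbered H3K4me3 and CTCF libraries in 1000 and 10000 cells, and of 0.0906 to 0.115 and 0.0852 to 0.116 for H3K27ac and Pol2S2P in 100 and 1000 cells. Not every pair passed the limit of 0.1 set for all of them, and the main tests took the libraries as unpaired. That limit does not rule out pairing, since column names place the number with the antibody pair, before the target read out. Same-numbered libraries of the same target across cell numbers had means of -0.00212, -0.00989, 0.00364 and -0.00315. Means for different numbers in dual stainings (-0.0348, -0.0263, -0.05 and -0.0485) follow from centring within each group and add no evidence. In all 4 dual stainings every library correlated best with its own number, which with the column names points to pairing. Within dual stainings the block gave 9321 and 7572 ends and 36533 and 15157 bins for H3K4me3 and CTCF in 10000 and 1000 cells, and 1499 and 441 ends and 6483 and 4031 interiors for H3K27ac and Pol2S2P in 1000 and 100 cells. With the block 121 H3K4me3 ends differed between cell numbers, and 5 ends and 32 bins between CTCF stainings.

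Leaving out 1 of 2 single libraries leaves that group with 1, whose spread then comes from the dual libraries alone. Leaving out each library in turn gave 8971 to 9428 and 7584 to 7947 ends for H3K4me3 against CTCF in 10000 and 1000 cells, and 29131 to 48149 and 15934 to 23562 bins. For H3K27ac against Pol2S2P it gave 1049 to 1137 and 262 to 404 ends in 1000 and 100 cells, and 5469 to 5711 and 3038 to 3201 interiors. Between cell numbers it gave 68 to 347 H3K4me3 ends, 31 to 84 CTCF bins, 0 to 3 H3K27ac ends and 0 to 5 Pol2S2P interiors. Between stainings it gave 0 to 2 CTCF ends, 0 to 4 CTCF bins, 3776 to 6102 Pol2S2P ends and 2051 to 3012 Pol2S2P interiors. The interactions gave 0 to 0 for the first pair of targets and 0 to 1 for the other. Differences in shares were 14.1 to 14.6, -16.0 to -15.3, 0.207 to 0.240 and 4.65 to 4.68 points in the order H3K4me3 ends, CTCF top bins, H3K27ac ends and Pol2S2P interiors, with a smallest possible p of 0.0556 each. For bins in 10000 cells the count higher in CTCF moved together with the number of bins tested, as given above. The cause of the other wide ranges was not tested.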

Other observations

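Carry-over between antibodies was weighed with a test written after the data were seen. CTCF with dual staining lay slightly above CTCF alone at marked ends that were higher in H3K4me3, with a median log2 fold change of 0.13 at 7150 ends against -0.01 at 5362 others. The difference of 0.142, which stayed between 0.109 and 0.160 without any 1 library, is consistent with some H3K4me3 reads in the dual CTCF libraries, but a wider opening of chromatin would give the same, and 0 single ends were called.

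H3K4me3 at marked ends was higher in 10000 than in 1000 cells. A uniform background in 1000 cells, planned before, predicted a flat fold over strongly marked ends, and the range over the upper 5 of 10 bands of ends ranked by H3K27ac count was 0.0743, which met that prediction. It also predicts folds that rise with H3K4me3 level, which rose over the bands from a median of 12.6 to 42.7 CPM, a check written after; the highest band instead lay below the lowest by 0.179 (difference -0.179, bootstrap SD 0.0179), with medians from 0.30 to 0.12. That later check alone speaks against uniform background as the sole cause, and it does not exclude it. The ends had passed a count filter on these same libraries, which can raise folds in the weak bands. Calls in this contrast ran from 68 to 347 with 1 library left out, and no such range is given for the bands.

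Pol2S2P lost share at marked ends with dual staining, and 3 explanations were tested, all written after the data were seen. With H3K27ac reads alone the share would lie between those of both sources; at marked ends it lay below the lower of them (difference -0.202 points, SD 0.0872), but it was close to it within 2.5 kb (8.72% against 8.81%, SD 0.130) and between them with both gene ends (8.59%, against at most 7.67% in any H3K27ac library of 1000 cells and a mean of 13.6% for Pol2S2P alone), so this test alone excludes nothing. A uniform background would shrink ends and interiors alike, yet the factors were 0.419 and 0.867 (difference 0.448), which excludes it as the sole cause. A mixture of single Pol2S2P with H3K27ac reads, uniform reads or both that holds the dual interior share could not go below 7.51% at marked ends, against 4.81% measured. With H3K27ac reads alone it would hold 11.9% within 2.5 kb and 11.7% at both ends, which excludes such mixtures as the whole cause. Some H3K27ac reads in the dual libraries stay possible. Marked ends higher in H3K27ac than Pol2S2P in 100 cells fell less with dual staining (median log2 fold change -0.82, 320 ends). Those lower in H3K27ac lay at -0.96 (109 ends) and all 10417 ends at -0.99. An effect of the second antibody was not separable from library preparation, which could differ between stainings.

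Chance arrangements of libraries were counted with splits planned before. For the 12 comparisons of 3 against 3 libraries there are 10 splits each, so a share under 0.05 could not be reached. In 11 of them the real split was 1 of 10 as large, with real counts of 9307, 7577, 36683, 15156, 1369, 431, 6081, 3667, 363, 93 and 2, and the highest other at 0 for each except 1 for the last, Pol2S2P interiors between cell numbers. For H3K27ac between cell numbers all 10 splits gave 0, the real one included. For the interactions the real count was 0, so 50 of 50 drawn splits were as large by construction, and the count says nothing about chance; the highest other was 56 for H3K4me3 and CTCF and 2 for H3K27ac and Pol2S2P. Cell number was permuted within each target, so a split can turn the difference between cell numbers (363 H3K4me3 ends) into an interaction. The split with 56 calls therefore need not point to any further structure of the samples, which was not tested.

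Pol2S2P reads were not confined to the marked end. The other gene end, 1.89% of the bins, held 4.78% of counts of Pol2S2P alone. In 1000 cells, density 10 kb inside long genes stood at 2.06 times the genome mean for Pol2S2P alone, 1.89 for dual Pol2S2P and 1.64 for H3K27ac. It was nearly as high 10 kb outside these genes, at 1.88, 1.71 and 1.58. Of the 1% of bins with the highest counts after thinning, 85.5% were distal for H3K27ac and 80.7% for Pol2S2P in 100 cells. In 1000 cells it was 77.2% for CTCF and 36.7% for H3K4me3, all below the 93.2% of all bins that are distal. Myod1 carried little H3K4me3 and H3K27ac while Myf5 carried much; whether this reflects the state of this C2C12 stock was not tested.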
